A study of Mus musculus with 23 samples.

How the data were processed

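The series holds 23 Affymetrix Mouse Genome 430 2.0 arrays of mouse epiblast-like cells, 1 for each genotype, condition and time. Per the labels, total RNA was amplified as cDNA and labelled with biotin, and cells were taken at 0 h and after 12, 24 and 36 h of aggregate culture. The deposited values are intensity values on a linear scale, 1 per probe set and array, and the method that made them is not given in the sources used here. All values lie on a grid of 0.01 in log2 with a floor at 1, where 2.93% of them stand. Array medians differed by 0.17 log2 and upper quartiles by 0.37. By a rule fixed before the data were examined, a spread above 0.2 log2 meant that log2(value + 16) was quantile normalized. There are no detection calls, so dim signal was not told apart from absence.

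Probe sets were named through the platform annotation given and matched to a reference table by gene identifier. Of 45101 probe sets 34958 name 1 gene, 932 several and 9211 none, and 34754 of those with 1 gene were matched. Probe sets with several genes or none were not used, and T, Nanos3 and some other list genes have no probe set that names them alone and are not analysed here. Of 18194 named genes each was represented by its probe set with the highest mean, and 13265 were kept because the signal exceeded the median of its array on at least 3 arrays. Of 311 genes in 24 lists fixed before the data were examined 249 were kept.

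Groups follow the sample titles. The model in limma 3.58.1 under R 4.3.3 used 21 arrays, 7 conditions and time as an additive block, which leaves 12 residual degrees of freedom, with empirical Bayes moderation along the mean signal. Each comparison is a mean over the 3 times, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. The additive block treats any change of a response with time as residual spread. Slopes came from a second model with a linear course per condition and 6 residual degrees of freedom. Arrays at 0 h enter no test. Gene lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, over 408 tests adjusted together. Of these 124 passed with the preset correlation, 8 with the estimated correlation and 99 with fry, and all 8 concern the BMP-SMAD list. Genes named are the 12 rising and 8 falling genes with the largest differences that passed and kept their direction at all 3 times, with gene models named by clone or locus numbers skipped, and members of the lists, besides Wnt3, response genes of both cytokines, Xist and Y-linked genes as checks of the labels.

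The steps were tested on simulated data with 13265 genes, 100 changed at each size. For BMP4 in WT 88% of genes changed by 1 log2 unit and 97% of those changed by 2 were called, and 14 of 199 calls were false, which is 7.04%. For the difference between genotypes of the BMP4 response the shares were 58% and 93%, with 10 of 161 calls false, for the slope in WT 68% and 94%, with 12 of 174 false, and for time 99% and 100%, with 7 of 206 false. In the list test the 1 shifted list of 24 was called and no unchanged one. The simulated genes varied independently of each other, so this does not test list calls among correlated genes.

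Alternatives fixed before the data were examined were values as deposited, median centring, offsets of 1 and 64, no filter or a filter at the 60th percentile, the mean of a gene's probe sets or each by itself, no trend in the prior variance, array weights, a fit of only the arrays compared, linear time courses per condition, an added 2-fold limit, leaving out each time, and exchanged labels of the 6 KO arrays. Added after the data were seen were the comparison of KO with BMP4 against WT with BMP4, fits without those 6 arrays, and fits without the 3 arrays of highest Gapdh 3' to 5' ratio. Scaling alternatives for the 0 h counts and the alternatives for the overlap were added then too. Those ratios were 4.03 for WT WNT3A at 24 h, 2.68 for KO without cytokine at 24 h and 2.30 for WT without cytokine at 36 h, and the others lay between 1.09 and 1.71. For 0 h, the median of a list was placed among 10000 random lists of genes of like mean signal. Each genotype is 1 line, so line and genotype cannot be told apart. Figures were drawn with matplotlib 3.10.9.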

Results

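Gene expression was measured in mouse epiblast-like cells, a culture model of the pregastrulation epiblast, made from male C57BL/6 embryonic stem cell lines with intact Wnt3 (WT) or without it (KO). Both lines carry a fluorescent reporter of Blimp1, a marker of germ cell specification. The cells were cultured as floating aggregates with no added cytokine, with BMP4 at 500 ng/ml or with WNT3A at 50 ng/ml, and the KO cells also with BMP4 and WNT3A together. Arrays cover 12, 24 and 36 h of culture and the cells at 0 h, 23 arrays in all, with 1 array per genotype, condition and time and no replicate at any of them. The array is the Affymetrix Mouse Genome 430 2.0 with 45101 probe sets, of which 13265 genes were tested. The median signal of an array lay between 36.8 and 41.4 and its upper quartile between 226 and 292. The number of arrays limits the precision. All differences below are means over the 3 times on the log2(signal + 16) scale with the standard error of the model (n = 3 times per condition), and this scale understates changes of dim genes. The 3 times stand in for replicates, and the spread of a gene is pooled over all 7 conditions. Each p-value thus sets a difference against how unsteady the gene was over the times in all conditions, within 1 series of cultures. For time in culture it sets the change against how unsteady it was over the 7 conditions. Genotype cannot be told apart from the single line that carries it.

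The labels were first checked against the arrays themselves. The Wnt3 probe set read between 11.2 and 27.9 in all KO arrays, and in WT arrays it reached 146 with BMP4 at 36 h. At 0 h it read 10.4 in WT and 16.2 in KO, and the deleted part of the gene is not given in the sources used here, so the probe set may lie outside it. Xist, which is expressed from an inactive X chromosome, stayed between 48.5 and 85.0, and the Y-linked gene Eif2s3y between 141 and 422. For 6 KO arrays the sample title, with the cytokine text and characteristics, and the array name in the description differ in the cytokines at all 3 times: arrays titled WNT3A are named for both cytokines, and arrays titled BMP4+WNT3A for WNT3A alone. Groups below follow the titles, and each such group is called by its title. Id1, a direct target of BMP signalling, read 5480, 7591 and 9345 at 12, 24 and 36 h in the KO arrays titled WNT3A, against 5557, 8192 and 10156 with BMP4 alone. In the KO arrays titled BMP4+WNT3A it read 186, 256 and 1323, against 189, 350 and 2077 in WT cells with WNT3A alone. These values go against the titles, so for each comparison that rests on the 6 arrays the main count of genes is also given with the labels exchanged.

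**Figure D1:**
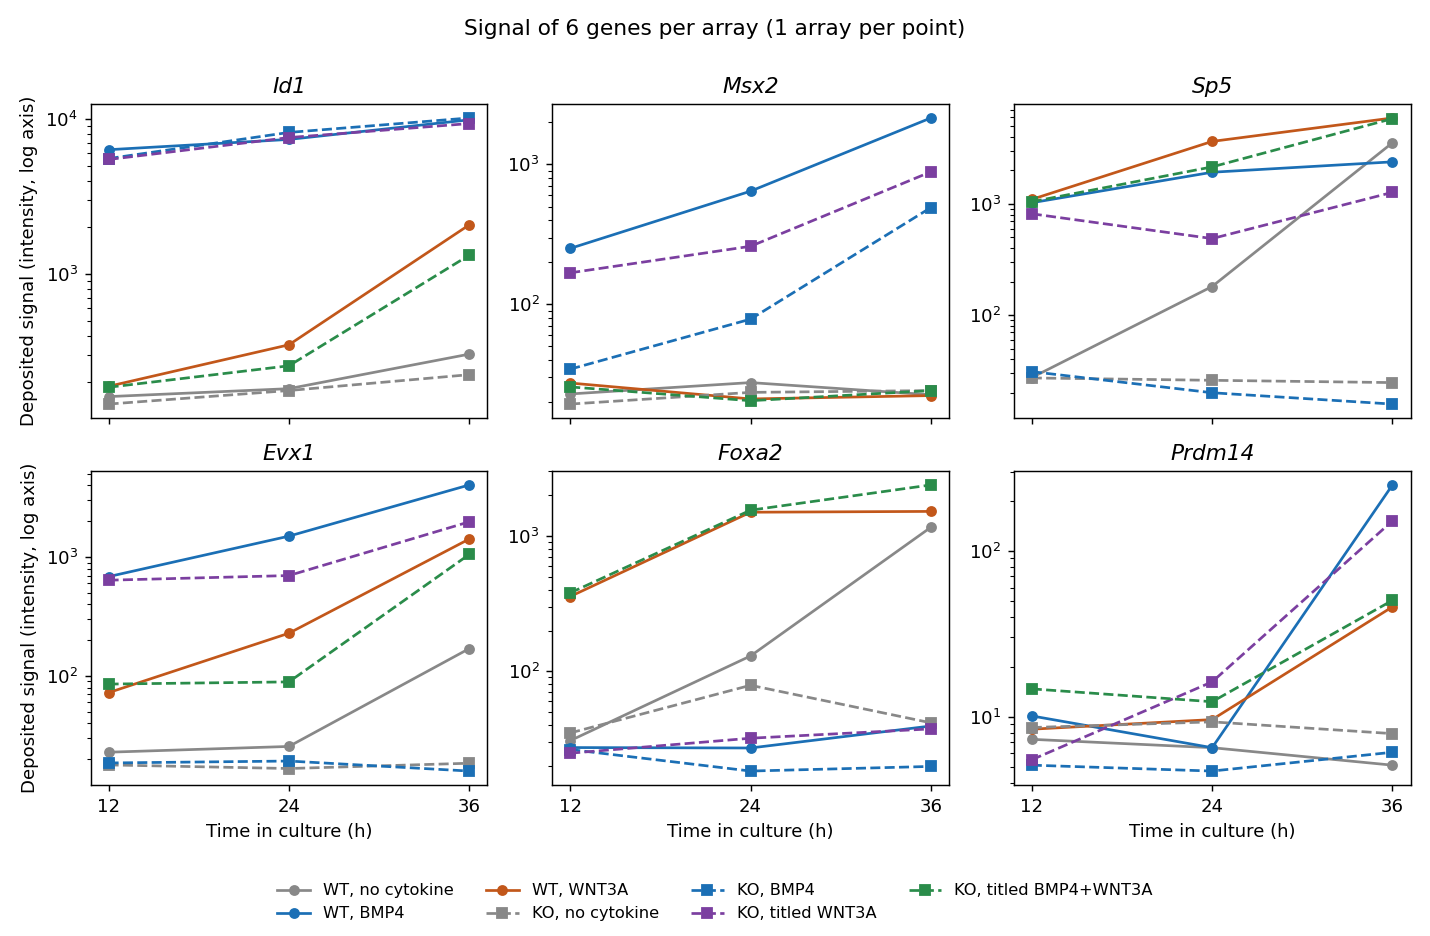
Deposited signal (log axis) of 6 genes at 12, 24 and 36 h, 1 point per array, lines joining the arrays of 1 condition (solid, WT; dashed, KO). Id1 follows BMP4 in WT and KO arrays and the KO arrays titled WNT3A lie on the same course, while Sp5 stays between 15.9 and 31.1 in KO arrays without cytokine or with BMP4.

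The first comparison asks what BMP4, the inducer of germ cell fate in this system, changed in WT cells. Id1 rose by 5.14 ± 0.43 (adjusted p = 6.84e-06), Id2 by 3.47 ± 0.26, and the homeobox genes Msx1 and Msx2 by 3.88 ± 0.33 and 4.21 ± 0.55. Evx1, a transcription factor of the posterior primitive streak, rose by 4.67 ± 0.59 (adjusted p = 0.000358) and Gata3 by 2.52 ± 0.58. Genes of the epiblast state fell: Pou3f1 by 2.86 ± 0.33, the growth factor gene Fgf5 by 2.69 ± 0.50 and Foxd3 by 2.07 ± 0.36, while the ectoenzyme gene Enpp3 fell by 3.59 ± 0.34. Of the 10 measured BMP-SMAD response genes 8 rose, none fell and 2 did not pass (9 adjusted over the list alone), with Id3 up 1.43 and Smad6, a feedback inhibitor of the pathway, up 1.90. The shift of this list passed with an estimated correlation as well (adjusted p = 0.00184). Of 13 primed epiblast genes 5 fell and 8 did not pass (9 fell adjusted over the list alone), Fgf15 by 2.03 and the DNA methyltransferase gene Dnmt3a by 0.87 among them, and the list's adjusted p was 0.0818 with an estimated correlation. Among 17 lateral and extraembryonic mesoderm genes 3 rose and 14 did not pass (3 adjusted over the list alone): Gata2 by 1.42, Gata4 by 1.25 and Tbx3 by 1.64 (adjusted p = 0.278 with an estimated correlation). Of 14 primitive streak genes Evx1 alone rose and 13 did not pass (4 adjusted over the list alone, adjusted p = 0.208 with an estimated correlation). Of 11 neural ectoderm genes Sox1 fell by 1.93 and Sox3 by 1.49, and 9 did not pass (3 fell adjusted over the list alone). Of 9 germline determinants and early germ cell genes none rose, Elavl2 fell by 1.07 and 8 did not pass (1 rose and 1 fell adjusted over the list alone), with Prdm1, which encodes Blimp1, at 0.99 ± 0.31 and Prdm14 at 1.25 ± 0.57. Across all genes limma called 453, 191 higher and 262 lower. Without the 24 h arrays 12 genes passed, without the 12 h arrays 167, without the 3 arrays with the highest Gapdh 3' to 5' ratio 253, and without the 6 KO arrays of conflicting labels 234. The WT array without cytokine at 36 h is among those 3.

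WNT3A in WT cells, the other signal that the study varied, gave fewer genes past the threshold than BMP4, a difference not tested. At an unadjusted p under 0.05 there were 1840 genes, against 2252 for BMP4. Wnt5b rose by 2.34 ± 0.43 (adjusted p = 0.0282), the guidance gene Ntn1 by 2.00 ± 0.40, Klhl32 by 2.46 ± 0.39 and the growth factor gene Pdgfa by 1.74 ± 0.33. Foxd3 fell by 2.09 ± 0.36, Slc35d3 by 2.11 ± 0.38 and the carbonic anhydrase gene Car4 by 1.82 ± 0.30. Of 15 posterior and presomitic mesoderm genes Wnt5b rose and 14 did not pass (6 rose adjusted over the list alone, adjusted p = 0.267 with an estimated correlation). Of 13 primed epiblast genes Pou3f1 fell by 1.64 and Dnmt3a by 0.81, and 11 did not pass (8 fell adjusted over the list alone, adjusted p = 0.0997 with an estimated correlation). Of 14 naive pluripotency genes Esrrb rose by 1.52 and Zfp42 by 0.63, and 12 did not pass (3 adjusted over the list alone, adjusted p = 0.189 with an estimated correlation). None of the 14 WNT-beta-catenin response genes passed over all genes (4 rose adjusted over the list alone, adjusted p = 0.189 with an estimated correlation). The reference cultures moved here: Sp5, a WNT target, read 27.5, 181 and 3541 at 12, 24 and 36 h in WT cells without cytokine, and 1098, 3641 and 5914 with WNT3A. In all 64 genes passed, 34 higher and 30 lower. The count was 268 without the 36 h arrays, 3 without the 12 h arrays and 0 without the 24 h arrays or without the 6 KO arrays of conflicting labels, and the WT WNT3A array at 24 h has the highest Gapdh ratio of the series at 4.03.

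In KO cells BMP4 raised the BMP targets, while genes of the WNT and streak lists mostly did not pass. Id1 rose by 5.31 ± 0.43 (adjusted p = 7.70e-06), Id2 by 3.74 ± 0.26, Id4 by 3.03 ± 0.37 and the phosphatase gene Dusp9 by 1.80 ± 0.23, while the matrix gene Dcn fell by 2.14 ± 0.34 and the glucose transporter gene Slc2a1 by 1.36 ± 0.20. Of the 10 BMP-SMAD response genes 6 rose and 4 did not pass (9 adjusted over the list alone), and the list passed with an estimated correlation (adjusted p = 0.00141). Of 11 p53 response genes Phlda3 rose by 0.61 and 10 did not pass (5 rose and 1 fell adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). None of the 9 germline genes passed (2 fell adjusted over the list alone). None of the 14 WNT-beta-catenin genes passed (1 rose adjusted over the list alone), and of 14 primitive streak genes Tdgf1, which encodes a Nodal coreceptor, rose by 1.17 while 13 did not pass (1 adjusted over the list alone). Most streak genes did not pass in WT either, but their mean moved further there. At 12 h the mean of the streak list stood at 6.82 without cytokine and 7.843 with BMP4 in WT, against 6.848 and 6.898 in KO. At 36 h it stood at 8.347 and 9.545 in WT, against 6.459 and 6.749 in KO. These are means of single arrays with no test, and those of the WNT list are given below. For BMP4 in KO 74 genes passed in all, 32 higher and 42 lower. Without the 24 h arrays none did and 39 did without the 12 h arrays, and without the 3 arrays of highest Gapdh ratio 24 did, the KO array without cytokine at 24 h being among them, and 26 did without the 6 KO arrays of conflicting labels.

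Whether the response to BMP4 depends on genotype was tested directly, as the difference of the 2 responses. No gene passed with limma (smallest adjusted p = 0.0516), while 781 genes had an unadjusted p under 0.05. Leaving out the 36 h arrays gave 29 genes, and without the 3 arrays of highest Gapdh 3' to 5' ratio 3 passed. Array weights and time trends per condition called genes as well, with counts given below. The absence of calls thus depends on the model and does not show that the responses were alike. As lists, the 13 primed epiblast genes had a median difference of 0.78 (KO response minus WT response, none passing over all genes and 3 adjusted over the list alone), with an adjusted p of 0.103 with an estimated correlation, and for the 8 core pluripotency genes, whose median was 0.63, it was 0.0547 (4 adjusted over the list alone). For the 14 primitive streak genes the median was -0.91 (2 lower and 1 higher adjusted over the list alone) and its adjusted p 0.328 with an estimated correlation.

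Set side by side with BMP4 present, KO and WT cells differed at many genes, a comparison added after the data were seen. It holds any difference already present without BMP4, so it does not measure the response to BMP4. At 36 h the mean of the WNT list stood at 8.66 in WT and 6.84 in KO without cytokine, and at 9.045 and 6.85 with BMP4. At 12 h it stood at 7.08 and 6.80 without cytokine, and at 8.14 and 6.84 with BMP4. Evx1 was lower in KO by -5.65 ± 0.59 (adjusted p = 7.49e-05), Sp5 by -5.52 ± 0.85, Tnfrsf19 by -4.99 ± 0.65, Wnt8a by -4.72 ± 0.60 and Axin2, a feedback inhibitor of WNT signalling, by -3.49 ± 0.48. Pou3f1 was higher in KO by 2.77 ± 0.33, Otx2 by 3.06 ± 0.52, Foxd3 by 2.95 ± 0.36 and Sox2 by 2.20 ± 0.36. Of 14 WNT-beta-catenin genes 8 were lower in KO and 6 did not pass (9 adjusted over the list alone, adjusted p = 0.0779 with an estimated correlation), Dkk1 among them at -2.81. Of 14 primitive streak genes 8 were lower and 6 did not pass (9 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), with Mixl1 at -3.54, Fgf8 at -3.28 and Eomes at -2.27. Of 13 primed epiblast genes 5 were higher and 8 did not pass (9 adjusted over the list alone, adjusted p = 0.0818 with an estimated correlation). Among the 10 BMP-SMAD genes only Msx1 and Msx2 were lower, both by -2.55, and 8 did not pass (4 adjusted over the list alone). Of 9 germline determinants and early germ cell genes Tfap2c was lower by -1.45, Elavl2 was higher and 7 did not pass (3 lower and 1 higher adjusted over the list alone). The 957 genes comprised 566 higher and 391 lower in KO. The count was 7 without the 24 h arrays, 465 without the 12 h arrays and 561 without the 6 KO arrays of conflicting labels.

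The KO arrays titled WNT3A held raised BMP targets and raised WNT targets together. Id1 rose by 5.22 ± 0.43 (adjusted p = 6.62e-06), Msx1 by 3.51 ± 0.33 and Evx1 by 4.84 ± 0.59, and so did Sp5 by 4.24 ± 0.85 and Tnfrsf19 by 4.53 ± 0.65. Slc35d3 fell by 4.29 ± 0.38, Fgf15 by 3.17 ± 0.42 and the neuronal tubulin gene Tubb3 by 3.31 ± 0.49. Of 10 BMP-SMAD genes 7 rose and 3 did not pass (9 adjusted over the list alone), which held with an estimated correlation (adjusted p = 0.00599). Of 14 WNT-beta-catenin genes 4 rose and 10 did not pass (4 adjusted over the list alone, adjusted p = 0.139 with an estimated correlation), Axin2 by 2.44 among them. Of 14 primitive streak genes 6 rose and 8 did not pass (8 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation), Fgf8 by 2.70 among them. Of 11 p53 response genes 6 rose and 5 did not pass (8 rose and 1 fell adjusted over the list alone, adjusted p = 0.16 with an estimated correlation), including the cell cycle inhibitor gene Cdkn1a by 2.01 and Perp by 1.53. Of 13 primed epiblast genes 7 fell and 6 did not pass (8 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation), Otx2 by 2.27 among them. Of 9 germline genes Tfap2c rose by 1.89, Kit and Elavl2 fell and 6 did not pass (4 rose and 2 fell adjusted over the list alone). In all 1260 genes passed, 529 higher and 731 lower. With the labels exchanged this group stands for both cytokines, and the count for WNT3A alone becomes 900. Without the 24 h arrays 98 passed, without the 12 h arrays 576, and without the 3 arrays of highest Gapdh ratio 681.

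The KO arrays titled BMP4+WNT3A held raised WNT targets, and no gene of the BMP-SMAD list passed as raised over all genes. Nkx1-2 rose by 5.75 ± 0.71 (adjusted p = 0.000297), Sp5 by 5.79 ± 0.85, Wnt8a by 5.02 ± 0.60, the Hox gene Hoxb1 by 4.99 ± 0.95 and Foxa2, a transcription factor of endoderm and axial mesoderm, by 4.07 ± 0.66. Foxd3 fell by 3.03 ± 0.36, Otx2 by 2.96 ± 0.52 and Id2 by 1.05 ± 0.26. Of 14 WNT-beta-catenin genes 7 rose and 7 did not pass (8 adjusted over the list alone, adjusted p = 0.0547 with an estimated correlation), with Axin2 up 2.80 and Lef1 up 1.09. Of 14 primitive streak genes 6 rose and 8 did not pass (11 adjusted over the list alone, adjusted p = 0.162 with an estimated correlation), Fgf8 by 2.93 and Snai1 by 1.79 among them. Of 15 posterior and presomitic mesoderm genes 4 rose and 11 did not pass (4 rose and 1 fell adjusted over the list alone, adjusted p = 0.376 with an estimated correlation), such as Wnt5b by 3.76 and Cdx1 by 3.62. Of 10 Hox genes 3 rose and 7 did not pass (4 adjusted over the list alone, adjusted p = 0.302 with an estimated correlation). Of 16 signalling ligands and antagonists 5 rose and 11 did not pass (8 adjusted over the list alone, adjusted p = 0.132 with an estimated correlation). None of the 10 BMP-SMAD genes rose over all genes, with Id1 at 1.02 ± 0.43 (adjusted p = 0.184), Id2 fell and 9 did not pass (2 rose, Msx1 at 1.10 and Smad6 at 0.51, and 1 fell adjusted over the list alone). Of 9 germline genes Tfap2c rose by 2.12 and Dnd1 by 1.32, Elavl2 fell and 6 did not pass (3 rose and 1 fell adjusted over the list alone). In all 900 genes passed, 396 higher and 504 lower, and exchanging the labels makes the count for both cytokines 1260. Without the 24 h arrays none passed, without the 12 h arrays 587, and without the 3 arrays of highest Gapdh ratio 415.

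**Figure D2:**
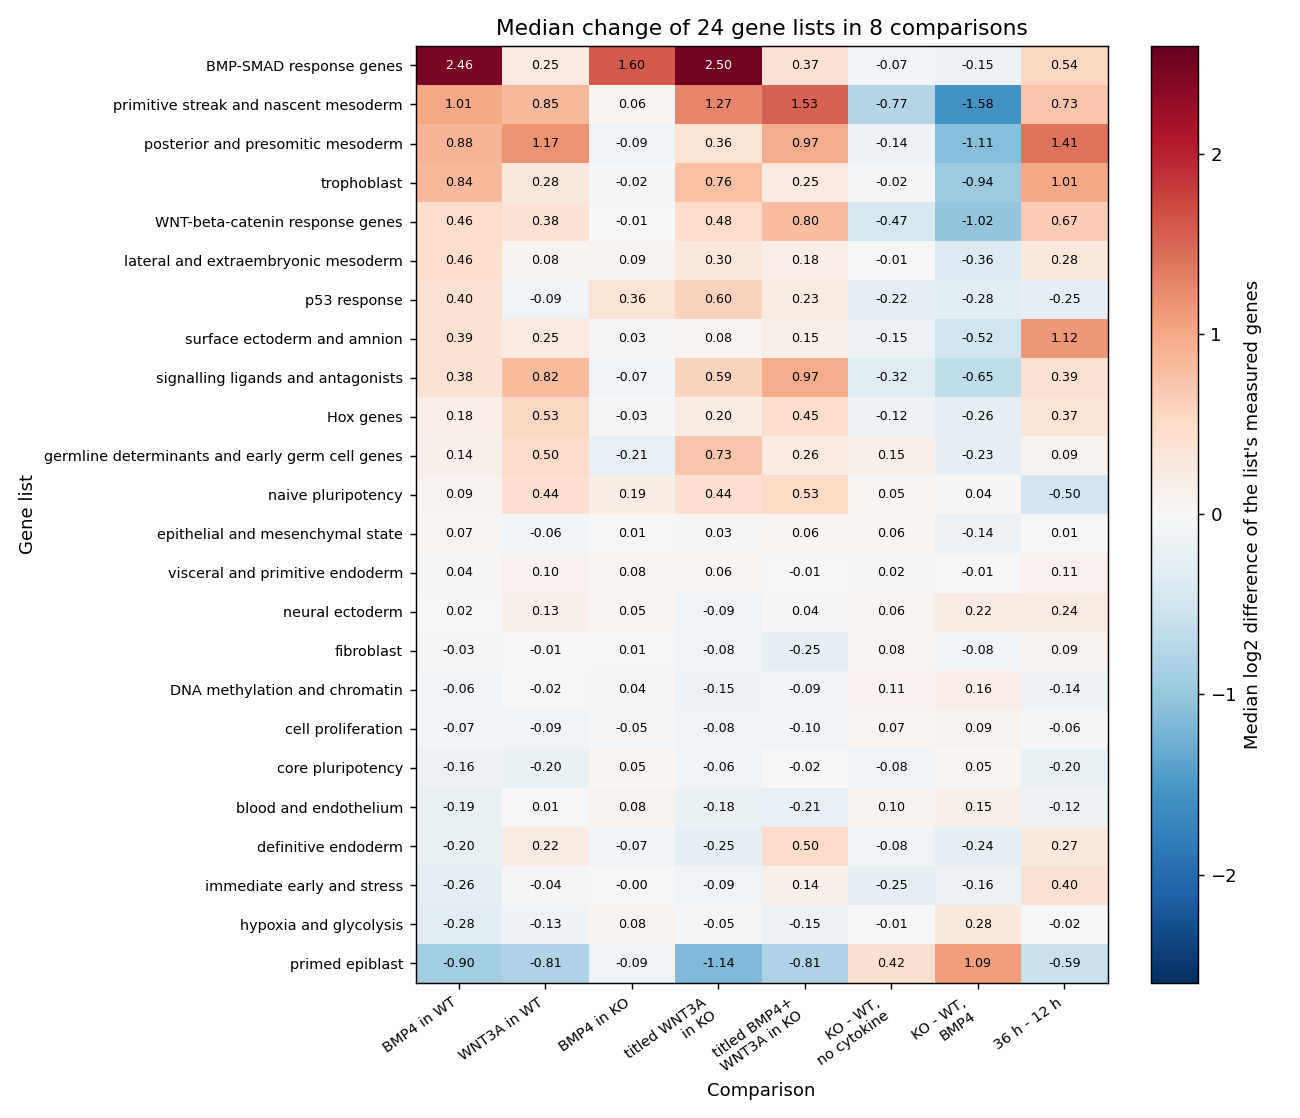
Median log2 difference of the measured genes of each of 24 lists (color and number) in 8 comparisons. The BMP-SMAD list stands at 2.46 with BMP4 in WT, 2.50 in the KO arrays titled WNT3A and 0.37 in those titled BMP4+WNT3A.

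Comparisons between the KO cytokine groups turn on the 2 labels. Taken by title, adding WNT3A to BMP4 raised Nkx1-2 by 6.40 ± 0.71 and Foxa2 by 4.91 ± 0.66, while Id1 fell by 4.28 ± 0.43 and Id2 fell by 4.79 ± 0.26 (adjusted p = 3.75e-08). Of the 10 BMP-SMAD genes 7 fell and 3 did not pass (8 adjusted over the list alone, adjusted p = 0.0384 with an estimated correlation). Among 1027 genes 489 rose and 538 fell. With exchanged labels 527 genes passed, and 376 were shared between both labellings. Nkx1-2 was then higher by 3.75 ± 0.71 (adjusted p = 0.00656), while Foxa2 at 0.35, Id1 at -0.09 and Id2 at -0.35 did not pass, and the shift of the BMP-SMAD list had an adjusted p of 0.216 with the preset correlation. For 8 other lists, primitive streak genes with a median of 1.20 and primed epiblast genes with -0.58 among them, the shift passed with the preset correlation and for none with an estimated one (lowest adjusted p 0.158). Taken by title, adding BMP4 to WNT3A changed 45 genes, 19 higher and 26 lower. Foxa2 rose by 4.55 ± 0.66, and Id1 fell by 4.19 ± 0.43, Id2 by 4.44 ± 0.26 and Msx2 by 3.17 ± 0.55. Of the 10 BMP-SMAD genes 7 fell and 3 did not pass (9 adjusted over the list alone), a call kept with an estimated correlation (adjusted p = 0.00121). Exchanging the labels turns each of these signs, so that Id1 is higher by 4.19 and Foxa2 lower by -4.55 when BMP4 is added. The interaction of both cytokines by title covered 230 genes, led by Id1 at -9.50 ± 0.61 and Id2 at -8.18 ± 0.37, with Foxa2 at 5.39 ± 0.93. Of 10 BMP-SMAD genes 9 were negative and 1 did not pass (9 adjusted over the list alone, adjusted p = 0.00121 with an estimated correlation). With exchanged labels limma called 0 genes for the interaction, with 360 at an unadjusted p under 0.05, and Id1 stood at -1.11, Id2 at 0.70 and Foxa2 at -3.72. The shifts of definitive endoderm, posterior mesoderm and WNT-beta-catenin genes then passed with the preset correlation, with medians of -0.13, -0.66 and -0.25, and none with an estimated one (lowest adjusted p 0.250). Without the 24 h arrays these 3 counts were 12, 1 and 7. Without the 12 h arrays the count for adding BMP4 was 24 and for the interaction 139, without the 36 h arrays the count for adding WNT3A was 645, and without the 3 arrays of highest Gapdh ratio the interaction covered 146 genes.

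KO cells titled with both cytokines were set against WT cells with BMP4, which asks how near KO cells with both cytokines stand to them. By title 125 genes differed, 74 higher and 51 lower in KO. Id1 was lower by -4.32 ± 0.43, Msx2 by -4.26 ± 0.55 and Evx1 by -2.96 ± 0.59, and Foxa2 was higher by 4.57 ± 0.66 and Fgf5 by 2.23 ± 0.50. Of 10 BMP-SMAD genes 8 were lower and 2 did not pass (10 adjusted over the list alone), with an adjusted p of 0.00141 with an estimated correlation. With exchanged labels 1 gene differed, with 758 at an unadjusted p under 0.05, and Id1 at -0.13, Msx2 at -1.09, Evx1 at -0.81, Foxa2 at 0.02 and Fgf5 at 1.03 did not pass. Some list shifts still passed with the preset correlation alone, though no list member passed over all genes. Naive pluripotency genes had a median of 0.56 (adjusted p = 2.00e-06), WNT-beta-catenin genes -0.32 (0.00181) and primed epiblast genes 0.31 (0.0138). DNA methylation and chromatin stood at 0.16 (0.0177), posterior mesoderm at -0.54 (0.0231), cell proliferation at 0.07 (0.0408) and core pluripotency at 0.10 (0.0488). With an estimated correlation none passed (lowest adjusted p 0.0961), so a difference of the 2 conditions as lists is not established. The same pair of responses overlapped by title in 73 genes that rose, against 5.70 expected from independent lists, and in 121 that fell, against 9.95 expected, while 2 genes moved in opposite directions. In the KO arrays titled WNT3A the overlap with the WT response to BMP4 was 142 genes that rose, against 7.62 expected, and 190 that fell, against 14.4. Without the 24 h arrays 1 gene differed and no gene was shared, and without the 12 h arrays 63 genes differed and 83 were shared.

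**Figure D3:**
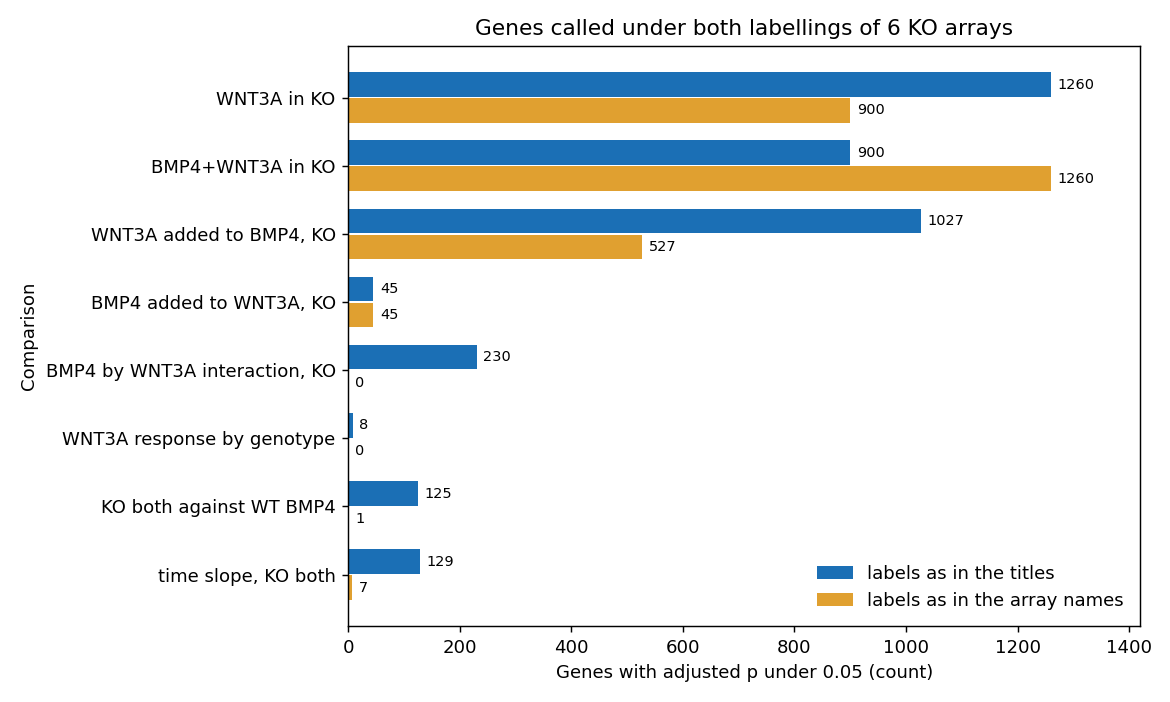
Number of genes with an adjusted p under 0.05 in 8 comparisons that use the 6 KO arrays of conflicting labels, with groups taken from the titles (blue) or from the array names (orange). The interaction goes from 230 to 0 genes and the difference of KO with both cytokines from WT with BMP4 from 125 to 1.

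The response to WNT3A differed between genotypes by title at 8 genes, 4 higher and 4 lower in KO. Id2 differed by 4.45 ± 0.37 (adjusted p = 2.26e-05), Id1 by 3.98 ± 0.61 and Smad6 by 1.53 ± 0.26, while the receptor activity modifier gene Ramp2 differed by -2.12 ± 0.35. Of 10 BMP-SMAD genes 3 were higher and 7 did not pass (9 adjusted over the list alone, adjusted p = 0.00472 with an estimated correlation). With exchanged labels limma called 0 genes, with 576 at an unadjusted p under 0.05: Id2 stood at 0.01, Id1 at -0.21, Smad6 at 0.11 and Ramp2 at -0.44, and the BMP-SMAD shift had an adjusted p of 0.801 with the preset correlation, while 5 other lists passed with it and none with an estimated correlation (lowest adjusted p 0.156). The count was 36 without the 36 h arrays, 0 without the 24 h arrays, 5 without the 12 h arrays and 3 without the 3 arrays of highest Gapdh ratio.

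Without cytokine KO and WT cells differed at 13 genes, 4 higher and 9 lower in KO. Frmd4a was higher by 2.97 ± 0.42 (adjusted p = 0.011) and Irs4, an adaptor of insulin signalling, by 1.68 ± 0.28. Erdr1 was lower by -1.31 ± 0.17, Cdkn1a by -1.48 ± 0.23 and Cenpx, a centromere protein gene, by -0.72 ± 0.11. None of the 14 WNT-beta-catenin genes passed (4 lower adjusted over the list alone), their median was -0.47, and the list's adjusted p was 0.0727 with an estimated correlation. None of the 14 primitive streak genes passed (1 lower adjusted over the list alone), with a median of -0.77 and an adjusted p of 0.246 with an estimated correlation. Of 11 p53 response genes Cdkn1a was lower and 10 did not pass (3 lower adjusted over the list alone, adjusted p = 0.277 with an estimated correlation). Without the 36 h arrays 38 genes passed, without the 24 h arrays or the 6 KO arrays of conflicting labels 0, and without the 3 arrays of highest Gapdh ratio, 2 of which belong to this comparison, 1.

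Time in culture, averaged over the 7 conditions, changed more genes than any other comparison. Such an average also takes in responses to the cytokines that changed with time, and it need not hold in each condition. From 12 to 36 h the pluripotency-associated genes Dppa2 fell by 3.25 ± 0.23 and Dppa4 fell by 3.15 ± 0.22, the germline genes Mael and Sycp3 by 3.21 ± 0.15 and 2.84 ± 0.15, and the DNA methylation cofactor gene Dnmt3l by 2.26 ± 0.11 (adjusted p = 1.23e-09). The apelin receptor gene Aplnr rose by 4.40 ± 0.76, the keratin genes Krt19 and Krt8 by 3.19 ± 0.36 and 2.03 ± 0.25, and Cdh2, Vim and Zeb2, genes of mesenchymal cells, by 1.95, 1.43 and 1.87. Of 15 posterior and presomitic mesoderm genes 11 rose and 4 did not pass (11 adjusted over the list alone, adjusted p = 0.448 with an estimated correlation), Rspo3 by 2.88 among them. The mean of this list went from 6.34 to 6.18 in KO without cytokine and from 6.21 to 6.09 in KO with BMP4. It rose in the other conditions, from 6.92 to 9.81 in WT with WNT3A and from 6.395 to 7.07 in WT without cytokine. Of 9 surface ectoderm and amnion genes 5 rose, 1 fell and 3 did not pass (5 and 1 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation). Of 14 naive pluripotency genes 5 fell and 9 did not pass (5 adjusted over the list alone, adjusted p = 0.328 with an estimated correlation). Of 13 primed epiblast genes 1 rose, 6 fell and 6 did not pass (1 and 8 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation), with Dnmt3a down as well: it fell by 1.29. Of 10 BMP-SMAD genes 7 rose, 1 fell and 2 did not pass (7 and 1 adjusted over the list alone, adjusted p = 0.277 with an estimated correlation), and of 17 lateral and extraembryonic mesoderm genes 5 rose, 2 fell and 10 did not pass (5 and 2 adjusted over the list alone, adjusted p = 0.48 with an estimated correlation). The mean of the BMP-SMAD list went from 9.20 to 10.37 in WT with BMP4 and from 6.87 to 6.93 in KO without cytokine.

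For the lists that follow the shift from 12 to 36 h did not pass, and with an estimated correlation it passed for no list at all. Of 9 germline genes 3 rose, Prdm14 by 1.20 and Tdrd7 by 1.21 among them, 3 fell, Dppa3 by 1.01 among them, and 3 did not pass (3 and 3 adjusted over the list alone). Of 12 immediate early and stress genes 6 rose, Fos by 2.14 and Egr1 by 1.32 among them, 2 fell and 4 did not pass (6 and 2 adjusted over the list alone). Of 12 DNA methylation and chromatin genes 1 rose, 5 fell and 6 did not pass (2 and 5 adjusted over the list alone), with Dnmt3b falling by 0.70 ± 0.15. Of 13 genes of epithelial and mesenchymal state 5 rose, 3 fell and 5 did not pass (5 and 4 adjusted over the list alone). Of 10 trophoblast genes 6 rose, 1 fell and 3 did not pass (7 and 1 adjusted over the list alone), and of 10 definitive endoderm genes 4 rose, 2 fell and 4 did not pass (4 and 2 adjusted over the list alone). Of 15 hypoxia and glycolysis genes 3 rose, 2 fell and 10 did not pass (3 and 2 adjusted over the list alone), and of 14 cell proliferation genes 3 rose, 5 fell and 6 did not pass (4 and 5 adjusted over the list alone). Of 9 blood and endothelium genes none rose, 4 fell and 5 did not pass (1 and 4 adjusted over the list alone), of 6 fibroblast genes 2 rose, 1 fell and 3 did not pass (3 and 1 adjusted over the list alone), and of 11 visceral and primitive endoderm genes 1 rose, 3 fell and 7 did not pass (1 and 3 adjusted over the list alone). Of 5127 genes in all 2365 rose and 2762 fell. That balance depends on scaling, since 74.9% of calls were higher as deposited and 64.1% after median centring, against 46.1% after quantile normalization. Without the 6 KO arrays of conflicting labels 3282 genes passed.

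The courses of the responses were compared as slopes against the untreated cells of the same genotype, in log2 per 12 h. In WT the BMP4 response grew for Mesp1, a gene of nascent mesoderm, by 3.11 ± 0.41 (adjusted p = 0.0127), Msx2 by 1.39 ± 0.22 and Gata4 by 1.27 ± 0.24. It shrank for Sp5 at -2.66 ± 0.37, Wnt8a at -2.08 ± 0.18, Nkx1-2 at -1.96 ± 0.24 and Nanog at -1.80 ± 0.28, and the Sp5 signal of untreated WT cells went from 27.5 to 3541 meanwhile. Of 17 lateral and extraembryonic mesoderm genes Gata4 had a positive slope and 16 did not pass (7 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). In WT 68 genes passed, 17 up and 51 down, and in KO 1 gene passed for BMP4, the neural gene Sox1 at -1.76 ± 0.18. For KO titled with both cytokines 129 genes passed, 101 up and 28 down, with Aplnr at 3.76 ± 0.54, Lhx1 at 2.20 ± 0.34 and Cdx2 at 2.13 ± 0.42. Of 15 posterior and presomitic mesoderm genes 5 had a positive slope there and 10 did not pass (11 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). With exchanged labels 7 genes passed, and Aplnr at 1.90, Lhx1 at 1.15 and Cdx2 at 1.00 did not. None of the 15 posterior and presomitic mesoderm genes passed then, and their median was 0.56 against 1.33 by title (adjusted p = 0.000209 with the preset correlation and 0.369 with an estimated one). Without the 3 arrays of highest Gapdh ratio these counts were 2 for WT with BMP4, 0 for KO with BMP4 and 285 for KO titled with both, and without the 6 arrays of conflicting labels WT gave 19.

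At 0 h the 2 lines are represented by 1 array each, so differences there have no test. As log2 differences on the same scale, 27 genes differed at least 2-fold, 14 higher and 13 lower in KO. The immediate early genes Fos and Egr1 stood higher in KO by 3.64 and 1.63, Parp4 by 2.51 and Frmd4a by 1.89, and Pabpc2 and Mro lower by -2.70 and -2.04. The immediate early and stress list had a median of 0.27, at percentile 100 of 10000 random lists matched on mean signal. Signalling ligands and antagonists had a median of 0.15, at percentile 99.98, blood and endothelium genes of 0.23, at percentile 99.5, and WNT-beta-catenin response genes of -0.18, at percentile 0.05. Random lists were drawn gene by gene, while genes of a list may move together between 2 single arrays. These percentiles thus do not measure how rare such a shift is. From 0 to 12 h without cytokine 92 genes changed at least 2-fold the same way in both genotypes, 39 up and 53 down. The hormone precursor gene Trh stood 3.13 higher at 12 h in WT and 3.50 higher in KO, and Egr1 stood at -2.28 in WT and -4.11 in KO. The naive pluripotency list had a median of -0.58 in WT and -0.42 in KO.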

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

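The tests of the 2 patterns weighed here were chosen only after the patterns were seen, and so were the regrouping of arrays for KO with BMP4 against WT with BMP4 and all regroupings within times. Responses that differed between groups, or with time, by a test of the difference itself are listed first. The WNT3A response differed by genotype at 8 genes by title: Id2 at 4.45, Id1 at 3.98, Smad6 at 1.53, Stoml3 at 0.91, Ramp2 at -2.12, AI662270 at -1.41, Trio at -0.92 and Akap9 at -0.71, of which Stoml3, AI662270, Trio and Akap9 are named here because the count is small. As list medians, this difference was 1.84 for BMP-SMAD response, 0.68 for p53 response and 0.51 for primitive streak genes. With an estimated correlation the call held for BMP-SMAD response (adjusted p = 0.00472) but not for p53 response (0.0997) or primitive streak genes (0.373). With exchanged labels and the preset correlation the BMP-SMAD shift had an adjusted p of 0.801, while p53 response with a median of 0.31 (1.59e-05) and primitive streak genes with 0.43 (0.00330) still passed, and so did WNT-beta-catenin response with 0.31 (0.000109; 0.125 by title), signalling ligands and antagonists with 0.20 (0.0356) and immediate early and stress genes with 0.22 (0.0368). None of these 5 passed with an estimated correlation (lowest adjusted p 0.156). The BMP4 response differed by genotype, in list medians, by 0.63 for core pluripotency, 0.33 for hypoxia and glycolysis, 0.78 for primed epiblast, -0.89 for posterior mesoderm and -0.91 for primitive streak genes, and for none of these 5 lists did the call hold with an estimated correlation. Time slopes of a response passed at 68 genes for BMP4 in WT, at 1 for BMP4 in KO and at 129 for KO titled with both cytokines, and the interaction in KO passed at 230. With exchanged labels limma called 0 genes for the interaction, with 360 at an unadjusted p under 0.05, and 0 for the WNT3A response by genotype, with 576.

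BMP-responsive genes were high in the KO arrays titled WNT3A and low in those titled BMP4+WNT3A. If the titles are right, induction of these genes by WNT3A with or without BMP4 leaves the low values unexplained. Arrays with both cytokines would then hold the BMP-SMAD list at or above BMP4 alone. Its median lay at -1.47, with 9 of 10 genes below 0. These low values are part of the pattern itself, so the outcome was fixed in advance and the test decides nothing. With exchanged labels it decides nothing either (Id1 at -0.09, Id2 at -0.35, adjusted p of the list 0.216 with the preset correlation). Exchanged labels remain a candidate explanation: over all genes the nearest array of the same time to those titled BMP4+WNT3A was WT with WNT3A at 12 h (r = 0.996) and 36 h (0.995) but KO titled WNT3A at 24 h (0.989, against 0.987 for WT with WNT3A, the array of highest Gapdh ratio at 4.03), and to those titled WNT3A it was WT with BMP4 at 24 h (0.992) and 36 h (0.977) but KO titled BMP4+WNT3A at 12 h (0.993, against 0.992 for WT with BMP4). Of 43 genes outside the list that BMP4 changed the same way in both genotypes 100% differed between the pair of conditions as a BMP4 response in the arrays titled WNT3A would, with a median of 0.66, and 42, 42 and 39 of them did so at 12, 24 and 36 h. An interplay of both cytokines, which the titles imply, is not excluded, since WT arrays exclude no interplay particular to KO cells. Against it stand the array names and the Id1 signals, which go with exchanged labels. Under those labels limma called 0 genes for the interaction, with 360 at an unadjusted p under 0.05, against 230 by title. Results by title that rest on these arrays are thus not established.

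WNT-responsive genes were high by 36 h in WT cultures without cytokine and stayed low in KO cultures, as for Sp5 with 3541 against 24.8. A wrong label of the WT array at 36 h cannot be told apart, since 9 of 14 list genes had moved further up in WT than in KO by 24 h, with an exact two-sided sign test p of 0.424, but the same test from 24 to 36 h gave 10 of 14 (exact p = 0.180) and is thus too weak to decide, and at 24 h Wnt8a read 787 in WT against 58.9 in KO and Nkx1-2 648 against 54.2. RNA quality may contribute, but its test cannot decide this. Over 21 arrays the Gapdh ratio and the list mean, both after condition and time, gave Pearson r = 0.487 (permutation p = 0.0251) and Spearman rho = 0.487 (permutation p = 0.0263). Pearson r was 0.510 without the 2 arrays farthest from the median, but 0.391 (permutation p = 0.0884) without the WT array at 36 h. The permutations treated the arrays as independent, although fitting condition and time had left fewer degrees of freedom. These permutation p-values are thus too low, and no conclusion is drawn from them. A difference of genotype or of line, which are confounded here, stays open: the slope of the list without cytokine was lower in KO with a list test p of 0.0142 with an estimated correlation, but this restates the pattern and favours no explanation.

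Other splits of the same arrays were counted for each comparison. For 13 comparisons only 10 splits exist, too few for a share under 0.05, so real counts and the highest of the other splits are given alone. The real count stood against the highest other at 453 and 1 for BMP4 in WT, 64 and 50 for WNT3A in WT, 74 and 2 for BMP4 in KO, 1260 and 0 for KO titled WNT3A, and 900 and 0 for KO titled with both. It stood at 1027 and 0 for adding WNT3A, 45 and 0 for adding BMP4, 13 and 1 for KO against WT without cytokine, 125 and 0 for KO titled with both against WT with BMP4, and 957 and 0 for KO against WT with BMP4. For slopes it stood at 68 and 484 for BMP4 in WT, 1 and 44 for BMP4 in KO, and 129 and 629 for KO titled with both, where 4, 2 and 2 of 10 splits gave as many genes, the real split included. Splits that call several times the real count point to a structure of the arrays. In each of these 3 slopes the highest other exchanges the 2 arrays of 12 h, which by construction turns a steady response into a slope. Of 100 splits drawn, 1 gave as many genes as the interaction (230, highest other 111) and 1 as many as time (5127, highest other 3320), the real split itself in both cases. For the WNT3A response by genotype 4 of 100 gave at least 8 genes, but the highest other was 356, again a sign of structure. Such splits exchange arrays of conditions that themselves differ, KO titled WNT3A from KO without cytokine at 1260 genes. How far this accounts for the high counts was not tested. These splits move arrays across times, although the model blocks on time. Where arrays were exchanged only within a time, 3 of 100 splits drawn gave as many genes as the interaction, with 1791 as the highest other, several times the real count, and 7 of 100 as many as the WNT3A response by genotype, with 272. Where 12 and 36 h were exchanged only within a condition, 1 of 64 gave as many genes as time, the real split itself, with 2339 as the highest other. For time a chance assignment of arrays within conditions can thus be excluded, but not a difference other than time that all arrays of a time share. For the WNT3A response by genotype chance is not excluded once times are kept. There too a split within times that calls 272 genes shows that the share is no plain measure of chance. For the interaction by title the shares are under 0.05, but a split within times that calls 1791 genes shows that these splits are no plain measure of chance, so chance is not taken as excluded there. For the BMP4 response by genotype all 100 gave at least the real count of 0 from limma, with 781 at an unadjusted p under 0.05, and the highest other was 693. Any split reaches a count of 0, so this decides nothing.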

How the results depend on the processing

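Alternatives without the 6 KO arrays of conflicting labels or the 3 arrays of highest Gapdh ratio, those for the overlap and 0 h, and the comparison of KO with WT under BMP4 were chosen after seeing the data. Of 4192 values of 249 named gene results 3530 kept direction and call, 645 kept direction without passing and 17 reversed, all with exchanged labels. Kept directions are no measure of robustness, since these genes were mostly named for passing with the same direction at all 3 times. Leaving out a time cannot turn such a direction, and several alternatives change only the spread. For adding BMP4, exchanged labels turn every sign by construction. Of 304 values of 21 counts 185 stayed within 1.5 times and 119 moved. Except where fewer arrays or genes enter, the cause was not tested. Low signal limits dim genes, as no background measure is given.

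As deposited, the BMP4 response by genotype counted 2 and the WNT3A response by genotype 5. Median centring gave 2 and 4. Offset 64 gave 3 for the BMP4 response by genotype and 43 for the WT slope, and offset 1 gave 0 for the KO BMP4 slope. No filter gave WNT3A in WT 31, adding BMP4 26, WNT3A by genotype 2, KO against WT without cytokine 7, the WT slope 15 and the slope with both 36. The 60th percentile gave 3 for BMP4 by genotype, the mean of probe sets 5 for WNT3A by genotype, and every probe set 32 for the WT slope. Without a variance trend the slopes were 20 and 66. The share of higher calls moved from 44.0% to 62.0% for KO titled with both as deposited, from 47.6% to 59.4% as deposited and 61.5% with centring for adding WNT3A, and from 59.2% to 81.1% and 81.3% for KO titled with both against WT with BMP4. For KO against WT with BMP4 it moved from 59.1% to 69.5% as deposited. The median of all genes moved by at most 0.0918, for time.

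Array weights gave WNT3A in WT 37, BMP4 in KO 168, titled WNT3A 2428, titled both 2005, adding BMP4 208, interaction 626, BMP4 by genotype 12, WNT3A by genotype 18, KO against WT without cytokine 5, titled both against WT BMP4 1032, KO against WT with BMP4 1437 and the slope with both 257. Fits of only the arrays compared gave BMP4 in WT 119, WNT3A in WT 0, BMP4 in KO 345, titled both 148, adding WNT3A 477, WNT3A by genotype 1, no cytokine 0, titled both against WT BMP4 18 and KO against WT with BMP4 118. Time trends per condition gave BMP4 in WT 941, WNT3A in WT 602, BMP4 in KO 226, titled both 1400, adding WNT3A 1585, adding BMP4 234, interaction 557, BMP4 by genotype 73, WNT3A by genotype 175, no cytokine 155, titled both against WT BMP4 414 and KO against WT with BMP4 1507. With a change of at least 2-fold BMP4 in WT had 164, WNT3A in WT 31, BMP4 in KO 39, titled WNT3A 318, titled both 301, adding WNT3A 310, interaction 152, WNT3A by genotype 5, no cytokine 6, titled both against WT BMP4 55, KO against WT with BMP4 243 and time 427.

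Leaving out each time in turn, counts ranged from 12 to 369 for BMP4 in WT, 0 to 268 for WNT3A in WT, 0 to 88 for BMP4 in KO, 98 to 1209 for titled WNT3A, 0 to 770 for titled both, 12 to 709 for adding WNT3A, 1 to 37 for adding BMP4 and 7 to 178 for the interaction. They ranged from 0 to 29 for BMP4 by genotype, 0 to 36 for WNT3A by genotype, 0 to 38 for no cytokine, 1 to 105 for titled both against WT BMP4, 7 to 846 for KO against WT with BMP4, 0 to 177 for the overlap and 72 to 118 for list shifts. Lists passed 124 times with a preset and 8 times with an estimated correlation.

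Exchanged labels gave 527 for adding WNT3A, 0 for the interaction and for WNT3A by genotype (limma, 360 and 576 at an unadjusted p under 0.05), 1 for titled both against WT BMP4, 7 for the slope with both and 332 for the overlap. Reversed were Id2 for WNT3A in KO (-1.05), Foxa2 (-0.48) and Id2 (3.39) for both, and for adding BMP4 Foxa2 (-4.55), Ntn1 (-2.05), Ackr3 (-1.80), Id1 (4.19), Id2 (4.44), Id4 (2.19), Msx1 (2.41) and Msx2 (3.17). Also reversed were Id2 (0.70), Msx2 (1.43) and Foxa2 (-3.72) for the interaction, Id1 (-0.21) for WNT3A by genotype, Id2 (0.15) against WT BMP4 and the Chrd slope (-0.070). Without the 6 conflicting arrays BMP4 in WT had 234, WNT3A in WT 0, BMP4 in KO 26, no cytokine 0, KO against WT with BMP4 561, time 3282 and the WT slope 19. Without the 3 arrays of highest Gapdh ratio BMP4 in WT had 253, WNT3A in WT 34, BMP4 in KO 24, titled WNT3A 681, titled both 415, interaction 146, BMP4 by genotype 3, WNT3A by genotype 3, no cytokine 1, the slopes 2 for WT, 0 for KO with BMP4 and 285 with both.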

Other observations

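The interferon test below was set out before its genes were looked at, and its values in the other responses, the slopes without cytokine and the chromosome test were chosen after the results were seen. Foxa2, a transcription factor of endoderm and axial mesoderm, had signals of 357, 1499 and 1520 at 12, 24 and 36 h in WT with WNT3A and of 380, 1552 and 2385 in KO titled BMP4+WNT3A. In WT with BMP4 it read 27.3, 27.1 and 39.4, and in KO titled WNT3A 24.8 at 12 h and 37.5 at 36 h. Without cytokine Foxa2 read 30.7, 129.8 and 1160.1 in WT and 35, 78.8 and 41.6 in KO. High Foxa2 at 36 h was thus not limited to WT with WNT3A and KO titled BMP4+WNT3A. Prdm14, a regulator of germ cell fate, read 249 in WT with BMP4 at 36 h and 151 in KO titled WNT3A, against 50.2 in KO titled BMP4+WNT3A, 45.9 in WT with WNT3A and 6.1 in KO with BMP4. Bmp4 itself read 2419 in WT with BMP4 at 36 h, 690 in WT with WNT3A, 744 in KO titled WNT3A, 648 in KO titled BMP4+WNT3A and 63.1 in KO with BMP4. These are signals of single arrays with no test.

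Without cytokine the time slope differed between genotypes at 25 genes, 22 lower and 3 higher in KO, which restates the WNT pattern weighed above. Sp5 differed by -3.21 log2 per 12 h, Nkx1-2 by -2.96, Tnfrsf19 by -2.65 and Wnt8a by -2.32, while Dcn differed by 1.26. The count was 29 as deposited, 32 after median centring, 18 without the 6 KO arrays of conflicting labels, and 7 without the 3 arrays of highest Gapdh 3' to 5' ratio, 2 of which belong to this comparison, with 6 of the 25 genes among the 7 and Sp5 at -2.46 (adjusted p = 0.149). Leaving out 1 of the 6 arrays at a time gave 4 genes without WT at 36 h, 2 without KO at 36 h, 43 without WT at 24 h, 34 without KO at 24 h, 35 without WT at 12 h and 19 without KO at 12 h, of which 4, 2, 25, 24, 12 and 7 were among the 25.

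Gbp3 at 1.82 and Igtp at 1.45 log2 per 12 h, both inducible by interferon, were among the genes whose BMP4 response in WT grew with time. The hypothesis of a shared interferon response was tested on other interferon-inducible genes, of which 37 of 51 were measured. Their median slope was 0.289 and 27 were above 0, with a list test p of 0.00945 with an estimated correlation, while Parp9 passed by itself at 0.85. It was not particular to BMP4 in WT: for KO titled with both cytokines the median slope was 0.370 (list test p of 0.00604 with an estimated correlation) and 4 passed, Parp9 at 1.11, H2-K1 at 0.61, Nmi at 1.44 and Irf1 at 1.04. With exchanged labels the median was 0.420 (list test p of 0.00165 with an estimated correlation), 34 of 37 were above 0 and Parp9 alone passed at 1.31, while Nmi at 1.51 (adjusted p = 0.0618) and Irf1 at 1.30 (adjusted p = 0.0579) missed the threshold with slopes no smaller than by title, and H2-K1 stood at 0.26. For BMP4 in KO the median was 0.0714 and none passed. From 12 to 36 h over all conditions 20 of the 37 rose, B2m by 1.33 and Rtp4 by 2.48 among them, and 1 fell, against 10 and 1 without the 6 KO arrays of conflicting labels. Other members went the other way: for BMP4 in WT Ifit2 stood at -0.18, Rsad2 at -0.089 and Cxcl10 at -0.24. The gene that fell from 12 to 36 h was Iigp1, at -0.36. A response shared by part of these genes may therefore be present, though its source was not tested.

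Genes that differ between the lines at every time could lie in a stretch of chromosome 11 carried along with the Wnt3 deletion. With a difference of at least 0.5 in each of 7 pairs of arrays 1 gene remained, Wnt5b on chromosome 6 with a mean of -2.50, so 0 lay on chromosome 11 where 0.0829 was expected. A minimum of 5 genes for this test was set after that count was seen, and the region was thus not testable.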
